A study of Paeonia lactiflora with 8 samples.

How the data were processed

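Small RNA of the herbaceous peony Paeonia lactiflora was measured in 8 libraries from 4 tissues, root, leaf, flower and fruit, with 2 libraries per tissue. The labels call the 2 libraries of a tissue biological replicates. They place root, leaf and flower at blossom and fruit at the young fruit stage, so tissue and stage cannot be separated for fruit. The libraries were made with a TruSeq small RNA kit and sequenced on a HiSeq instrument, per the labels' protocols. The same protocols speak of more small RNA libraries than the 8 used here; any others, and the messenger RNA and degradome data named in the series title, were not analysed here.

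The deposited values are normalized read counts, per the file headers, and were treated as a signal. The headers do not say how the values were scaled. Scaling by 1 factor per library was inferred from the steps given below. Per the labels' protocols, reads passed through the program ACGT101-miR, which removed adapter dimers, low-complexity reads, repeats and common RNA families such as ribosomal and transfer RNA. Per the deposited column legend, reads were mapped to hairpins of selected species in miRBase and, for some groups of miRNAs, to a genome, and a miRNA's value came from all reads of its isoforms. The normalization formula, the program versions and the genome build are not given in the sources used here. Within each library, between 69.8% and 79.4% of the values above 0 were whole multiples of 1 step, within 0.01 of a step, and between 92% and 97% were multiples when shares of 1 in 2 were also accepted. The step, taken as the value of 1 read, ran from 0.432 in flower 1 to 2.54 in root 2. It was used only to state depth and the value of 3 reads. Because reads appear to have been split between loci, whole reads were not recovered and no count model was used.

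The implied depth, the summed value divided by the step, was 178083 reads in root 1, 73898 in root 2, 254828 in leaf 1, 331706 in leaf 2, 519033 in flower 1, 724509 in flower 2, 128476 in fruit 1 and 201512 in fruit 2. A value of 3 reads corresponded to 4.27 in root 1, 7.62 in root 2, 3.15 in leaf 1, 2.23 in leaf 2, 1.3 in flower 1, 2.22 in flower 2, 4.19 in fruit 1 and 2.77 in fruit 2. These floors cover counting error only.

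The deposited table held 304 entries with 270 different mature sequences. Entries with an identical sequence were counted as 1 miRNA under the first name, a choice made after seeing the data, and testing each entry by itself was run as an alternative. Names are printed as deposited. The prefix gives the species of the matching miRBase entry, L and R give bases added or missing at the left and right end, and ss gives substitutions with their position from the 5' end. Names with MIR and p3 or p5 mark an arm of a known hairpin that the authors describe as newly observed, and names with PC mark miRNAs that the authors predicted without a match to a miRBase hairpin. No genome position is given for any miRNA here, because no genome was used beyond the authors' own mapping.

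The tests, thresholds, lists and naming rule were set before the data were examined. The plan named a count model for counts and limma for normalized values, and the values called for limma. The 216 miRNAs with a value of at least 1 in at least 2 libraries were tested, and 54 were not. Values were turned into log2(value + 1) and fitted with limma 3.58.1 in R 4.3.3, with all 8 libraries, tissue as the only term, and empirical Bayes moderation with a mean-variance trend. The fit had 4 residual degrees of freedom and 2.43 prior degrees of freedom. A miRNA was called at a Benjamini-Hochberg adjusted p under 0.05 over the 216. The 6 pairs of tissues were compared, and an F test asked for any tissue difference. A miRNA was counted as highest in a tissue when it was called and higher there in all 3 pairs that hold that tissue. Log2 differences are on the log2(value + 1) scale, which understates changes of low values. A fold is the ratio of the mean values of the 2 tissues, and no fold is given against a tissue whose libraries were both listed at 0.

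The lists were made from the family number in each name and group families by their best-known targets in other plants. They were phase change, auxin, developmental transcription factors, copper, nutrient, silencing machinery, NLR immune receptors, MYB, and the predicted miRNAs, 9 lists in all. A list of animal names was a control for foreign sequence, and 0 of the miRNAs carried such a name. Each list was tested in each pair of tissues with limma's camera at a preset correlation of 0.01, with adjustment over the 54 combinations, and again with the correlation estimated from the data. Within a list, calls were also counted with p adjusted over the list alone.

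The named miRNAs were, for each pair with root, the 10 largest rises and 10 largest falls among called miRNAs whose libraries did not overlap and whose mean in the higher tissue was at least 10. For the other pairs they were the 5 largest each way. The rule also took up to 5 miRNAs highest in each tissue, the 10 most abundant, and the 4 most abundant members of each list. Members called only with adjustment over a list alone were named after their values were seen.

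The test was run on simulated data with changes put into leaf and read between root and leaf. There were 20 simulations of 216 miRNAs, with 14 changed miRNAs at each fold. The test recovered 8.21% of 4-fold changes, 53.6% of 16-fold changes and 87.1% of 64-fold changes, and 4.36% of its calls were wrong. Each miRNA was drawn with the same spread in every library, and only abundant miRNAs were changed. In the data, root replicates differed more than leaf replicates, and most root and leaf calls had a tissue at 0. These rates therefore need not hold for the calls in the data. The fitted changes had a slope of 0.895 against those put in. The list test called the auxin list, with every member raised in leaf by 3 log2 units, in 20 of 20 simulations. It called 0 of 1080 unshifted combinations. Noise was drawn independently for each miRNA, so these simulations do not test the preset correlation, and smaller shifts were not tried. In 100 further simulations of 216 miRNAs with no tissue difference, the mean number of calls per pair was 0.0667 and the largest was 3. A miRNA highest in a tissue appeared in 1 of those simulations, although the 3 pairs behind such a call share libraries. These simulations also gave every tissue the same spread, so their counts need not hold for the data.

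The alternatives were quantile normalization, median-of-ratios scaling, no filter, a minimum value of 10, pseudocounts of 0.5 and 10, limma without the trend, a block for the replicate number, only the 2 tissues compared, and each library left out. For the lists, families were summed or the correlation was estimated. Library weights, entries as deposited and lists of known mature names only were added after seeing the data. Against the values as deposited, median-of-ratios scaling moved the median log2 change of all miRNAs by between -0.126 and 0.003 over the 6 pairs. Quantile normalization moved it by between -0.475 and 0.188. Every directed change of a named miRNA kept its sign under both. This is a weak check, since these changes were picked as called ones whose libraries do not overlap. Figures were drawn with matplotlib 3.10.9.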

Results

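MicroRNAs of about 21 nt, which guide the cleavage or repression of matching messenger RNAs, were profiled in root, leaf, flower and fruit of Paeonia lactiflora. The series asks how regulation differs between tissues that differ in paeoniflorin, the monoterpene glucoside for which peony root is used medicinally. Each tissue had 2 libraries (n = 2), described as biological replicates. The file listed 270 different mature sequences, of which 112 were 21 nt and 56 were 18 nt long. The summed normalized read count per library was 253333 and 187782 in root, 267174 and 246133 in leaf, 224292 and 536567 in flower, and 179334 and 185844 in fruit. Between 139 miRNAs, in fruit 1, and 189, in flower 1, had a value above 0. Target functions named below are background from other plants and were not measured here.

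A few miRNAs made up most of the mean profile over the 4 tissues. The 10 most abundant miRNAs held 78.3% of the mean total. Among them ath-miR159a (TTTGGATTGAAGGGAGCTCTA), which targets GAMYB transcription factors, had 35.4% of the mean total, and bdi-miR166a-3p (TCGGACCAGGCTTCATTCCCC), which targets class III HD-ZIP genes of leaf polarity, had 15.4%. ath-miR159a averaged 48560 ± 3912 in root, 65710 ± 12980 in leaf, 191000 ± 167900 in flower and 63290 ± 11970 in fruit (SD, n = 2). Its share of a library's total ran from 20.3% in root 1 to 57.7% in flower 2, with 32.2% in flower 1, and in leaf 1 bdi-miR166a-3p was ahead of it, at 27.7% against 21.2%. The rest of the 10 were vvi-miR167b, ath-miR168a-5p, gma-miR396a-5p, ath-miR157a-5p_2ss12TG15AG, gma-miR6300_R+5, PC-5p-97_25693, ath-miR171a-3p_1ss17AG and csi-miR164. The sequence of gma-miR6300_R+5 (GTCGTTGTAGTATAGTGGTAAGT) resembles the 5' end of plant aspartate transfer RNA, and its values were 8454 and 28999 in the root libraries. None of these 10 was called by limma in the F test for any tissue difference, where 67 of the 216 miRNAs had an unadjusted p under 0.05 and 10 were called.

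Replicates differed most in root. Across miRNAs, which are not independent replicates, Pearson's r between the 2 libraries on the log2 scale was 0.692 in root, 0.915 in leaf, 0.867 in flower and 0.861 in fruit. For miRNAs with a mean of at least 100, the median fold between replicates was 3.2 in root, 1.42 in leaf, 2.97 in flower and 1.58 in fruit. In root 2, sequences of 18 and 19 nt held 16% of the total, against 1.46% in root 1 and at most 1.93% in any other library. Most of this was the 19-nt ath-miR396b-5p_R-2, named here after its values were seen, at 21185 in root 2 and 99.6 in root 1, or 11.3% of the root 2 total. Without it the share was 4.72% in root 2, 1.42% in root 1 and at most 1.67% elsewhere. The 18-nt sequences that end in CCA, as mature transfer RNAs do, held 3.61% of root 2 and 0.54% of root 1. The known miR168 and miR164 were examples of the spread: ath-miR168a-5p, which targets AGO1, was 45382 and 2312 in root, and csi-miR164, which targets NAC genes, was 16197 and 119.

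**Figure D1:**
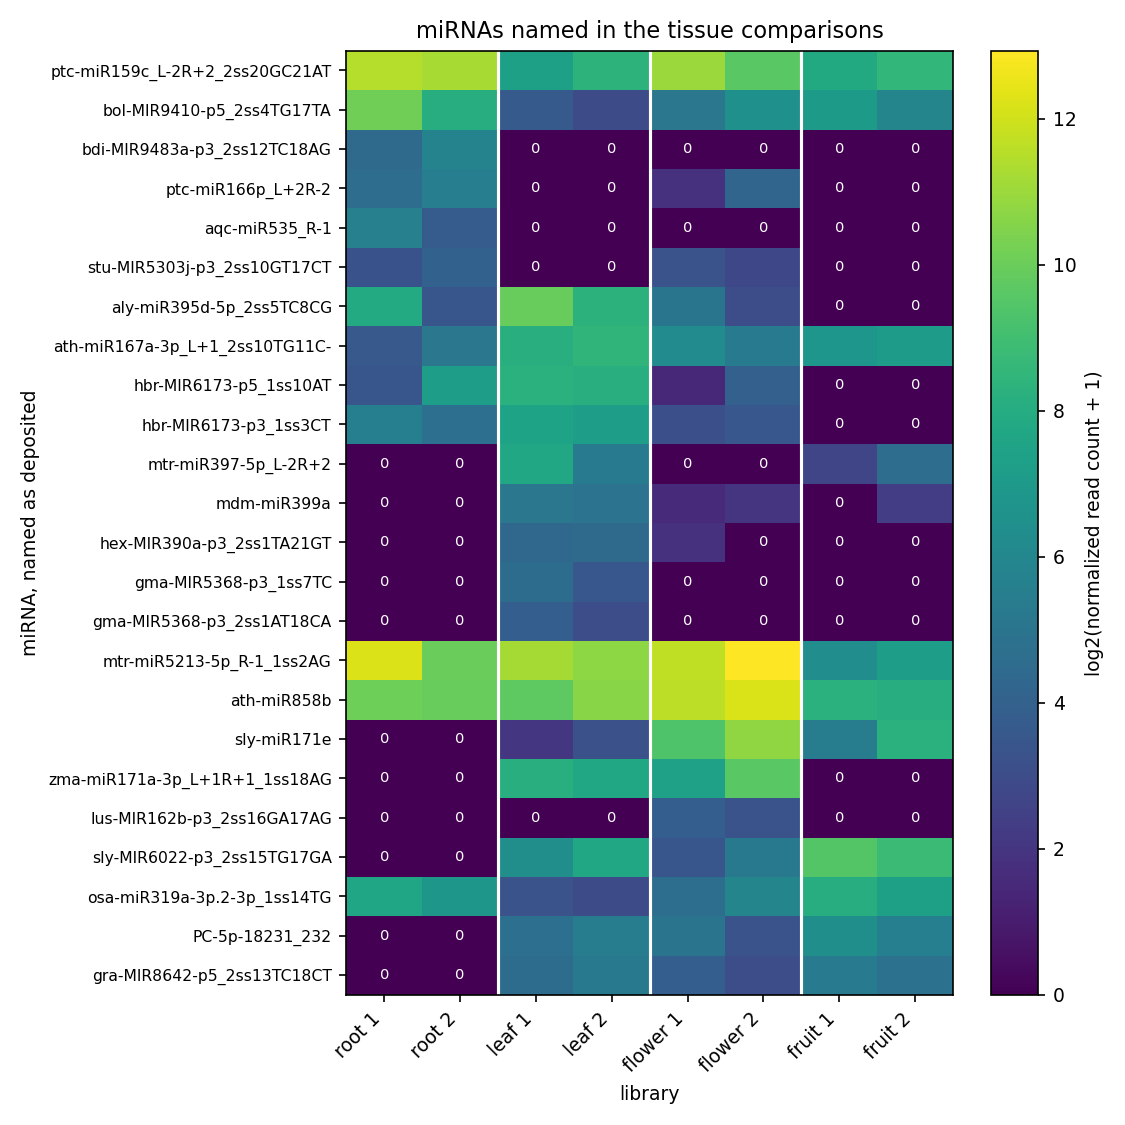
Normalized read counts of the 24 miRNAs named in the pairwise comparisons, as log2(value + 1) by colour, in each of the 8 libraries; a printed 0 marks a value listed at 0. Most rows hold a tissue in which both libraries are listed at 0, such as root and fruit for zma-miR171a-3p_L+1R+1_1ss18AG.

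Root was first set against leaf. In leaf, a member of the miR171 family, which targets GRAS genes of the SCARECROW-LIKE group, and a member of the miR397 family, which targets laccases, were present, and in root they were listed at 0. The 22-nt zma-miR171a-3p_L+1R+1_1ss18AG (CTGATTGAGCCGCGCCAGTATC) was 278 and 209.6 in leaf and 0 and 0 in root (adjusted p = 0.0243, limma). It is 1 base longer at the 5' end than the family's most abundant form, ath-miR171a-3p_1ss17AG, which was 1586 and 1605 in root and 6605 and 4662 in leaf and was not called. Another family member, lja-miR171c, named after its values were seen, was 920 and 25.4 in root and 0 and 0 in leaf and was not called (adjusted p = 0.0659, limma). mtr-miR397-5p_L-2R+2 (ATTGAGTGCAGCGTTGATGAA) was 216 and 40.8 in leaf and 0 and 0 in root (adjusted p = 0.0346, limma). Root was higher in a miR159 variant and a miR319, whose relatives target GAMYB and TCP genes. ptc-miR159c_L-2R+2_2ss20GC21AT was 2844 and 2387 in root and 163 and 328 in leaf, 10.7-fold higher, with a log2 difference of 3.49 ± 0.78 (SE, adjusted p = 0.0441, limma). osa-miR319a-3p.2-3p_1ss14TG was 19.3-fold higher in root, with a log2 difference of 4.07 ± 0.87 (SE, adjusted p = 0.0411, limma). The far more abundant ath-miR159a was 51323 and 45790 in root and 56531 and 74883 in leaf and was not called (adjusted p = 0.816, limma). ath-miR319a, named after its values were seen, was 9049 and 2445 in root and 134 and 110 in leaf and was not called (adjusted p = 0.0694, limma).

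In all, 18 miRNAs were called between root and leaf by limma, 7 higher in root and 11 higher in leaf, and 47 had an unadjusted p under 0.05. The largest difference without a 0 was in bol-MIR9410-p5_2ss4TG17TA, at 1106 and 267 in root and 11.5 and 6.68 in leaf, 75.4-fold, a sequence that was not checked against ribosomal, transfer or plastid RNA. Both libraries of the lower tissue were listed at 0 for 14 of the 18. On the root side these included bdi-MIR9483a-p3_2ss12TC18AG, at 21.3 and 53.4, ptc-miR166p_L+2R-2, at 23.8 and 45.7, aqc-miR535_R-1, at 48.4 and 12.7, and stu-MIR5303j-p3_2ss10GT17CT, at 8.54 and 15.2. On the leaf side they included sly-MIR6022-p3_2ss15TG17GA, at 81.8 and 217, PC-5p-18231_232, at 25.2 and 43.8, and gra-MIR8642-p5_2ss13TC18CT, at 23.1 and 36.4. mdm-miR399a, whose family targets the phosphate regulator PHO2, was 33.6 and 28.9 in leaf. The gma-MIR5368-p3_1ss7TC sequence was 23.1 and 10.4 in leaf and gma-MIR5368-p3_2ss1AT18CA was 13.6 and 7.42. The latter and hbr-miR396a_R-3, at 6.29 and 7.67, lie within the 3-read floor of 7.62 in root 2 in at least 1 leaf library, so their absence from root 2 was not detectable at this depth. They lie above the floor of 4.27 in root 1.

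By list, the auxin miRNAs did not pass as a group between root and leaf (camera adjusted p = 0.278, limma). Of 19 auxin miRNAs, 0 rose and 2 fell in root over all miRNAs tested, and 1 rose and 5 fell adjusted over the list alone. ath-miR167a-3p_L+1_2ss10TG11C-, from the opposite arm of the hairpin of miR167, was 11.4 and 34.3 in root and 281 and 352 in leaf, 13.9-fold lower in root, with a log2 difference, root minus leaf, of -3.92 ± 0.87 (SE, adjusted p = 0.0441, limma). hex-MIR390a-p3_2ss1TA21GT, from the hairpin of miR390, was 18.9 and 20.8 in leaf and 0 and 0 in root. The miRNAs added by the list alone were vvi-miR167b, at 557 and 1495 in root and 33594 and 34830 in leaf, vvi-miR393a_R+1, at 354 and 167.7 against 3620 and 3987, gma-MIR393a-p3, and, higher in root, ath-miR160a-3p_1ss16TA, at 316 and 556 against 73.4 and 63.8. miR167 and miR160 target auxin response factors and miR393 targets the auxin receptors TIR1 and AFB. Of 6 copper miRNAs, 1 fell over all miRNAs tested and 3 fell adjusted over the list alone, the added ones being ath-miR408-3p_L-1R+1_2ss12CT15CT, at 7.11 and 0 in root and 624 and 404 in leaf, and aly-miR398a-3p_R-2. Of 14 nutrient miRNAs, 1 fell over all miRNAs tested and 2 fell adjusted over the list alone, mdm-miR399a and mdm-miR395a. Of 45 developmental transcription factor miRNAs, 3 rose and 2 fell over all miRNAs tested, and likewise adjusted over the list alone. Of 19 predicted miRNAs, 1 fell under both, and as a list they were lower in root (camera adjusted p = 0.0238, limma; adjusted p = 0.602 with an estimated correlation). In the other 4 lists, with 40 members, limma called 0 either way and 2 had an unadjusted p under 0.05.

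The root and leaf calls depended on single libraries: 44 miRNAs were called without root 1, 16 without root 2, 0 without leaf 1, 0 without leaf 2, 17 without flower 1, 1 without flower 2, 0 without fruit 1 and 10 without fruit 2. Quantile normalization called 10, no filter called 2, and library weights and a fit of root and leaf alone called 0 each, with 33 to 48 miRNAs at an unadjusted p under 0.05 in the fits that called 0.

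Among the miRNAs called between root and flower, a pair of miR171 family members had the largest differences. sly-miR171e (TTGAGCCGCGTCAATATCTCT) was 658 and 1776 in flower and 0 and 0 in root (adjusted p = 0.0178, limma). zma-miR171a-3p_L+1R+1_1ss18AG was 167.7 and 787 in flower and 0 and 0 in root (adjusted p = 0.0178, limma). The most abundant form of the family, ath-miR171a-3p_1ss17AG, was 1586 and 1605 in root and 5789 and 23044 in flower and was not called. The 18-nt lus-MIR162b-p3_2ss16GA17AG was 13.4 and 8.89 in flower and 0 and 0 in root (adjusted p = 0.0213, limma). Higher in root were bdi-MIR9483a-p3_2ss12TC18AG, at 21.3 and 53.4 (adjusted p = 0.0193, limma), and aqc-miR535_R-1, at 48.4 and 12.7 (adjusted p = 0.0317, limma), both listed at 0 in flower.

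Limma called 6 miRNAs between root and flower, 2 higher in root and 4 higher in flower, with 35 at an unadjusted p under 0.05, and all 6 were listed at 0 in both libraries of one tissue. ptc-miR390a_R+1, at 4.75 and 4.44 in flower, lies within the floor of 7.62 in root 2, so its absence was not detectable there, and lies above the floor of 4.27 in root 1. Of 45 developmental transcription factor miRNAs, 2 fell in root over all miRNAs tested and 3 fell adjusted over the list alone, the added one being aly-miR171c-5p_1ss11GC, at 0 and 5.08 in root and 122 and 817 in flower. Of 19 auxin miRNAs, 1 fell under both, ptc-miR390a_R+1. Of 10 silencing machinery miRNAs, 1 fell under both, lus-MIR162b-p3_2ss16GA17AG, which is in the list by name alone. In the other 6 lists, with 69 members, limma called 0 either way and 9 had an unadjusted p under 0.05. The count was 24 without root 1, 10 without root 2, 0 without leaf 1, 0 without leaf 2, 1 without flower 1, 0 without flower 2, and 3 without fruit 1 or fruit 2. Quantile normalization called 3, no filter called 2, a minimum value of 10 called 2, a pseudocount of 10 called 0, limma without the trend called 3, and library weights and a fit of root and flower alone called 0, with 17 to 32 at an unadjusted p under 0.05 in the fits that called 0.

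Between root and fruit, sly-MIR6022-p3_2ss15TG17GA was 708 and 452 in fruit and 0 and 0 in root (adjusted p = 0.0167, limma). sly-miR171e was 44 and 304 in fruit and 0 and 0 in root, and the predicted PC-5p-18231_232 was 85.1 and 47 in fruit and 0 and 0 in root (adjusted p = 0.0444 for each, limma). Higher in root were hbr-MIR6173-p3_1ss3CT, at 46.9 and 25.4 (adjusted p = 0.0444, limma), bdi-MIR9483a-p3_2ss12TC18AG (adjusted p = 0.0289, limma) and aqc-miR535_R-1 (adjusted p = 0.0444, limma), each listed at 0 in both fruit libraries. The MIR6173 and MIR9483 sequences were not checked against ribosomal, transfer or plastid RNA, so they may not be miRNAs.

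Limma called these 6 miRNAs between root and fruit, 3 higher on each side, with 34 at an unadjusted p under 0.05. Of 19 predicted miRNAs, 1 fell in root over all miRNAs tested and 2 fell adjusted over the list alone, PC-5p-18231_232 and PC-3p-503_5584, the latter at 506 and 219 in root and 3481 and 2866 in fruit. As a list they were lower in root (camera adjusted p = 0.0141, limma; adjusted p = 0.602 with an estimated correlation). Of 45 developmental transcription factor miRNAs, 1 fell over all miRNAs tested, and 1 rose and 2 fell adjusted over the list alone, ptc-miR166p_L+2R-2 being higher in root and ath-miR396b-5p_R-2_2ss18AT19CT and sly-miR171e higher in fruit. Of 9 miRNAs on the NLR immune receptor list, 0 were called over all miRNAs tested and 1 adjusted over the list alone, gra-MIR482d-p5_1ss3CA. The list holds only families set beforehand, so miRNAs of other families with such targets may lie outside it. Among the 9, gra-MIR482d-p5_1 and gra-MIR482d-p5_2 had identical values in every library, so they are not separate measurements. In the other 6 lists, with 70 members, limma called 0 either way and 7 had an unadjusted p under 0.05. The count was 29 without root 1, 19 without root 2, 0 without leaf 1, leaf 2, fruit 1 or fruit 2, and 1 without flower 1 or flower 2. Quantile normalization called 1, with 0 higher in root and 1 higher in fruit, no filter called 1, a pseudocount of 0.5 called 10 and of 10 called 0, and library weights and a fit of root and fruit alone called 0, with 24 to 32 at an unadjusted p under 0.05 in the fits that called 0.

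Between leaf and flower, sly-miR171e was 3.15 and 8.16 in leaf and 658 and 1776 in flower, 215-fold higher in flower. Its log2 difference, leaf minus flower, was -7.46 ± 1.23 (SE, adjusted p = 0.0389, limma). lus-MIR162b-p3_2ss16GA17AG was listed at 0 in leaf and was 13.4 and 8.89 in flower (adjusted p = 0.0389, limma). The gma-MIR5368-p3_1ss7TC and gma-MIR5368-p3_2ss1AT18CA sequences were higher in leaf and listed at 0 in flower (adjusted p = 0.0389 for each, limma). The phase change miRNA ath-miR157a-5p_2ss12TG15AG, whose family targets SPL genes of the juvenile to adult transition, was 52.4 and 17.8 in leaf and 45306 and 24954 in flower, but it was not called (adjusted p = 0.117, limma).

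Limma called 5 miRNAs between leaf and flower, 2 higher in leaf and 3 higher in flower, with 46 at an unadjusted p under 0.05. The copper families target copper proteins such as plantacyanin, laccase and Cu/Zn superoxide dismutase. Of 6 copper miRNAs, 0 were called over all miRNAs tested and 4 rose in leaf adjusted over the list alone. They were ath-miR408-3p_L-1R+1_2ss12CT15CT (TGCACTGCCTTTTTCCTGGCT), at 624 and 404 in leaf and 0 and 16.3 in flower, mtr-miR397-5p_L-2R+2, at 216 and 40.8 against 0 and 0, tcc-miR398a, at 696 and 15.5 against 2.77 and 0, and aly-miR398a-3p_R-2. As a list the copper miRNAs did not pass (camera adjusted p = 0.054, limma; adjusted p = 0.602 with an estimated correlation). Of 19 auxin miRNAs, 1 was higher in flower over all miRNAs tested, and adjusted over the list alone 2 were higher in leaf, vvi-miR393a_R+1 and hex-MIR390a-p3_2ss1TA21GT, and 2 in flower, ptc-miR390a_R+1 and ath-miR390a-3p_1ss8CT. Of 45 developmental transcription factor miRNAs, 1 was higher in flower under both, sly-miR171e. Of 10 silencing machinery miRNAs, 1 was higher in flower under both, lus-MIR162b-p3_2ss16GA17AG, which is in the list by name alone. In the other 5 lists, with 63 members, limma called 0 either way and 12 had an unadjusted p under 0.05. The count was 21 without root 1, 20 without root 2, 0 without leaf 1, leaf 2, flower 1 or flower 2, and 1 without fruit 1 or fruit 2. A fit of leaf and flower alone called 19 and library weights called 14, while quantile normalization, no filter, a minimum value of 10, a pseudocount of 10 and limma without the trend each called 0, with 19 to 42 at an unadjusted p under 0.05 in the fits that called 0.

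**Figure D2:**
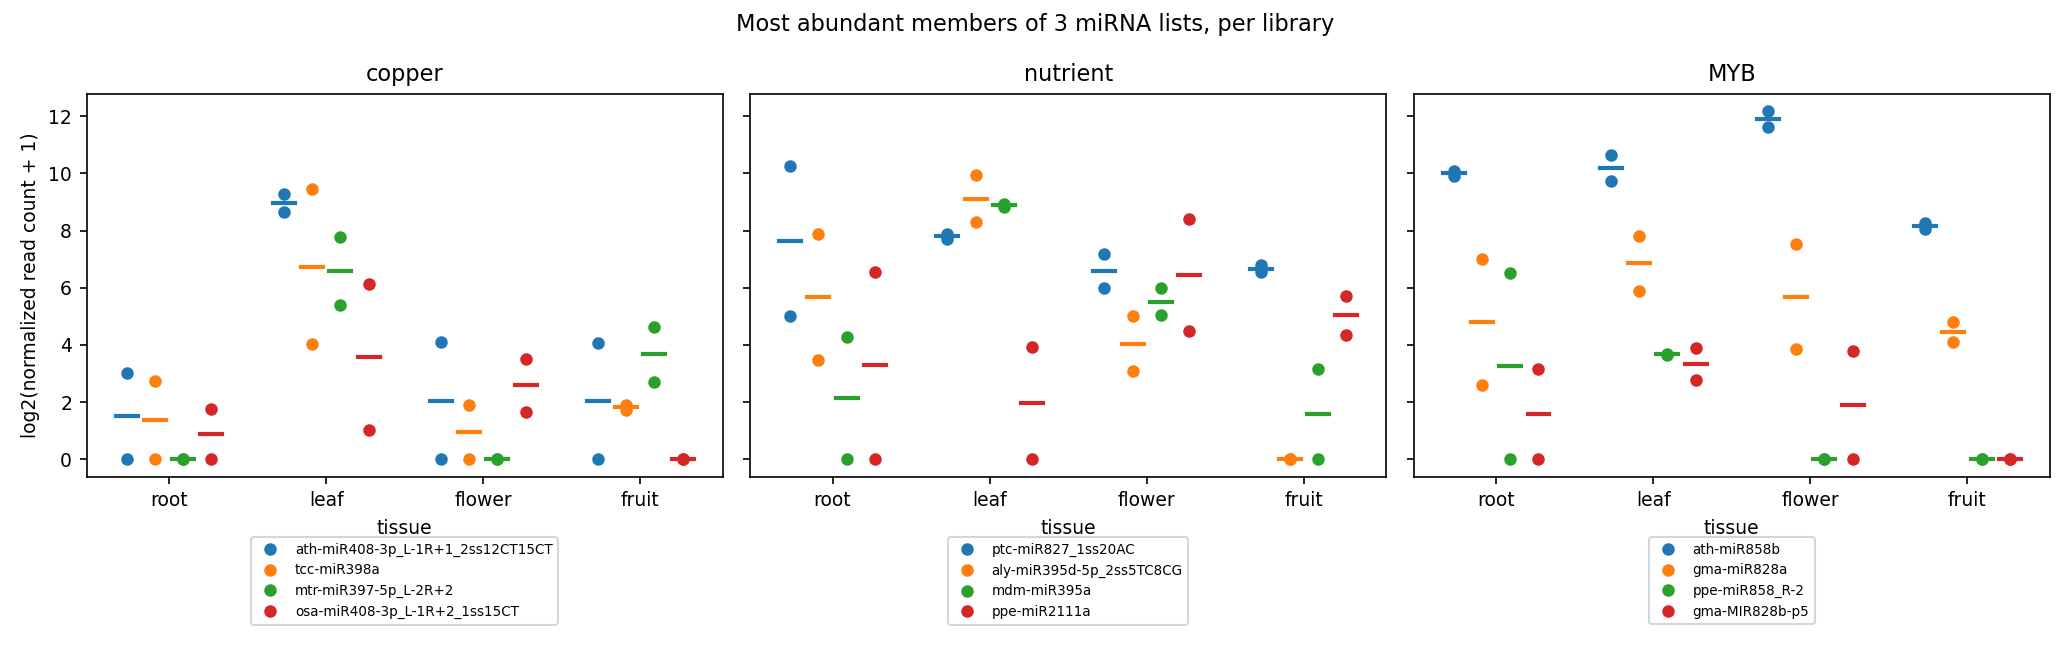
The 4 most abundant members of the copper, nutrient and MYB lists in each tissue, as log2(normalized read count + 1); each point is a library and each bar the mean of the 2 libraries. ath-miR408-3p_L-1R+1_2ss12CT15CT lies at 624 and 404 in leaf and at most at 16.3 in any library of the other tissues.

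Between leaf and fruit, most called miRNAs were higher in leaf. aly-miR395d-5p_2ss5TC8CG, from the opposite arm of the hairpin of miR395, whose mature strand targets ATP sulfurylases, was 974 and 315 in leaf and 0 and 0 in fruit (adjusted p = 0.0437, limma). zma-miR171a-3p_L+1R+1_1ss18AG was 278 and 209.6 in leaf and 0 and 0 in fruit (adjusted p = 0.0271, limma). The form 1 base shorter at the 5' end, ath-miR171a-3p_1ss17AG, was 6605 and 4662 in leaf and 290 and 3274 in fruit and was not called. Further called miRNAs listed at 0 in fruit were hbr-MIR6173-p5_1ss10AT, at 305 and 275 in leaf, hbr-MIR6173-p3_1ss3CT, at 182 and 149.9, and hex-MIR390a-p3_2ss1TA21GT, at 18.9 and 20.8. The sequence of hbr-MIR6173-p5_1ss10AT begins with the 9 bases with which that of hbr-MIR6173-p5 ends. The MIR6173 sequences were not checked against ribosomal, transfer or plastid RNA, so they may not be miRNAs. Higher in fruit was osa-miR319a-3p.2-3p_1ss14TG (TTGGACTGAAGGGGGCTCCC), at 261 and 163 against 9.04 and 7 in leaf, 26.5-fold, with a log2 difference, leaf minus fruit, of -4.53 ± 0.87 (SE, adjusted p = 0.0437, limma).

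Limma called 8 miRNAs between leaf and fruit, 7 higher in leaf and 1 higher in fruit, with 41 at an unadjusted p under 0.05. Of 14 nutrient miRNAs, 1 was higher in leaf over all miRNAs tested and 6 were higher in leaf adjusted over the list alone. Besides aly-miR395d-5p_2ss5TC8CG these were mdm-miR395a, at 485 and 455 in leaf and 0 and 7.84 in fruit, mdm-miR399a, and the miR169 members nta-miR169b, sbi-miR169e and aly-MIR169d-p5_2ss6TG17TA, which target NF-YA genes. As a list the nutrient miRNAs did not pass (camera adjusted p = 0.0725, limma; adjusted p = 0.602 with an estimated correlation). Of 45 developmental transcription factor miRNAs, 1 was higher and 1 lower in leaf over all miRNAs tested, and 2 were higher and 3 lower adjusted over the list alone. The lower ones were osa-miR319a-3p.2-3p_1ss14TG, ppe-MIR319a-p5 and ath-miR396b-5p_R-2_2ss18AT19CT. Of 19 auxin miRNAs, 1 was higher in leaf under both, hex-MIR390a-p3_2ss1TA21GT. In the other 6 lists, with 65 members, limma called 0 either way and 10 had an unadjusted p under 0.05. The count was 30 without root 1, 29 without root 2, 0 without leaf 1, leaf 2, fruit 1 or fruit 2, and 2 without flower 1 or flower 2, with 24 to 41 at an unadjusted p under 0.05 in the fits that called 0. A fit of leaf and fruit alone called 47 miRNAs, 35 higher in leaf and 12 in fruit, library weights called 44, a minimum value of 10 called 4 and no filter called 2, while quantile normalization called 7, 5 higher in leaf and 2 in fruit.

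Between flower and fruit, all called miRNAs were higher in flower. ath-miR858b (TTCGTTGTCTGTTCGACCTTG), which targets R2R3-MYB genes of phenylpropanoid metabolism, was 3138 and 4664 in flower and 308 and 267 in fruit, 13.5-fold higher, with a log2 difference of 3.73 ± 0.65 (SE, adjusted p = 0.0462, limma). mtr-miR5213-5p_R-1_1ss2AG was 3267 and 7796 in flower and 78.9 and 148 in fruit, 48.7-fold higher, with a log2 difference of 5.53 ± 0.97 (SE, adjusted p = 0.0462, limma). Its family is on none of the 9 lists, so no list count covers it. zma-miR171a-3p_L+1R+1_1ss18AG was 167.7 and 787 in flower (adjusted p = 0.0356, limma) and lus-MIR162b-p3_2ss16GA17AG was 13.4 and 8.89 (adjusted p = 0.0425, limma), both listed at 0 in fruit. The shorter miR171 form, ath-miR171a-3p_1ss17AG, was 5789 and 23044 in flower and 290 and 3274 in fruit and was not called. ath-miR157a-5p_2ss12TG15AG differed between the fruit libraries, at 29.3 in fruit 1 and 15531 in fruit 2, and was not called.

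Limma called 5 miRNAs between flower and fruit, 5 higher in flower and 0 higher in fruit, with 35 at an unadjusted p under 0.05. Of 5 MYB miRNAs, 1 was higher in flower under both adjustments, over all miRNAs tested and adjusted over the list alone, ath-miR858b, while gma-miR828a was 183 and 13.3 in flower and 27.2 and 16.1 in fruit. Of 10 silencing machinery miRNAs, 1 was higher in flower over all miRNAs tested, and 1 was higher and 1 lower adjusted over the list alone. The higher one was lus-MIR162b-p3_2ss16GA17AG, in the list by name alone. The lower one was mes-miR403a_1ss19TC, which targets AGO2, at 821 and 404 in flower and 3802 and 3718 in fruit. Of 19 auxin miRNAs, 1 was higher in flower over all miRNAs tested and 2 adjusted over the list alone, ptc-miR390a_R+1 and ath-miR390a-3p_1ss8CT. Of 14 nutrient miRNAs, 0 were called over all miRNAs tested and 1 was higher in flower adjusted over the list alone, sbi-miR169e. Of 45 developmental transcription factor miRNAs, 1 was higher in flower under both, zma-miR171a-3p_L+1R+1_1ss18AG. In the other 4 lists, with 50 members, limma called 0 either way and 4 had an unadjusted p under 0.05. The count was 18 without root 1, 17 without root 2, 1 without flower 1, and 0 without leaf 1, leaf 2, flower 2, fruit 1 or fruit 2. Quantile normalization, no filter and a minimum value of 10 called 1 each, limma without the trend called 2, library weights called 8, and a pseudocount of 10 and a fit of flower and fruit alone called 0, with 19 to 44 at an unadjusted p under 0.05 in the fits that called 0.

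Few miRNAs stood highest in a single tissue by all 3 of its comparisons. Root had 2, bdi-MIR9483a-p3_2ss12TC18AG and aqc-miR535_R-1 (TGACAACGAGAGAGAGCACGC). Leaf had 2, both gma-MIR5368-p3 forms, and flower had 2, lus-MIR162b-p3_2ss16GA17AG and ptc-miR390a_R+1. The MIR9483 and MIR5368 sequences were not checked against ribosomal, transfer or plastid RNA, so they may not be miRNAs. The sequence of lus-MIR162b-p3_2ss16GA17AG does not resemble miR162. For gma-MIR5368-p3_2ss1AT18CA and ptc-miR390a_R+1, the 0 in root 2 lies within that library's floor of 7.62, so it does not show a lower level there. Fruit had 0 by limma, and 1 at an unadjusted p under 0.05 in each pair. All 6 were listed at 0 in every library of the other tissues, and their highest value in any library was 53.4. Another miR535 entry, ppe-MIR535a-p5_2ss12GA18CT, named after its values were seen, was above 0 in every library and was not called in any pair. It was 99.6 and 33 in root, 26.2 and 20 in leaf, 2.59 and 8.15 in flower, and 12.6 and 4.61 in fruit. Libraries at 0 added no spread to the fit, and a 0 can hide a spread below the floor. The standard error ran from 0.44, in ptc-miR390a_R+1, to 0.78, in aqc-miR535_R-1, against a median of 1.33 over all miRNAs. The p-values of these 6 may therefore be too small. The F test called 10 miRNAs, these 6 and sly-miR171e, zma-miR171a-3p_L+1R+1_1ss18AG, sly-MIR6022-p3_2ss15TG17GA and hbr-MIR6173-p3_1ss3CT (adjusted p from 0.0305 to 0.0499, limma). It called 53 without root 1, 43 without root 2, 1 without flower 1 or fruit 1, and 0 without leaf 1, leaf 2, flower 2 or fruit 2. Without leaf 1, leaf 2, flower 1, flower 2, fruit 1 or fruit 2 in turn, 0 miRNAs were highest in any tissue. Without root 1 the numbers were 4 in root, 5 in leaf and 4 in flower, and without root 2 they were 1 in root, 6 in leaf, 2 in flower and 1 in fruit.

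Across the 9 lists and 6 pairs, 2 of the 54 combinations passed with camera at the preset correlation, both for the predicted miRNAs, and 0 passed with an estimated correlation, where 2 had an unadjusted p under 0.05. The calls numbered 0 without root 1 or fruit 1, 3 without root 2, leaf 2 or flower 1, and 5 without leaf 1, flower 2 or fruit 2. The smallest camera adjusted p of limma was 0.527 for the 16 phase change miRNAs, 0.278 for auxin, 0.0694 for developmental transcription factors, 0.165 for silencing machinery, 0.183 for NLR immune receptors and 0.199 for MYB. The median, the mean and the test of a list differed in sign in 11 of the 54 combinations, 5 of them in the phase change list, and in 0 of the 2 that passed.

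**Figure D3:**
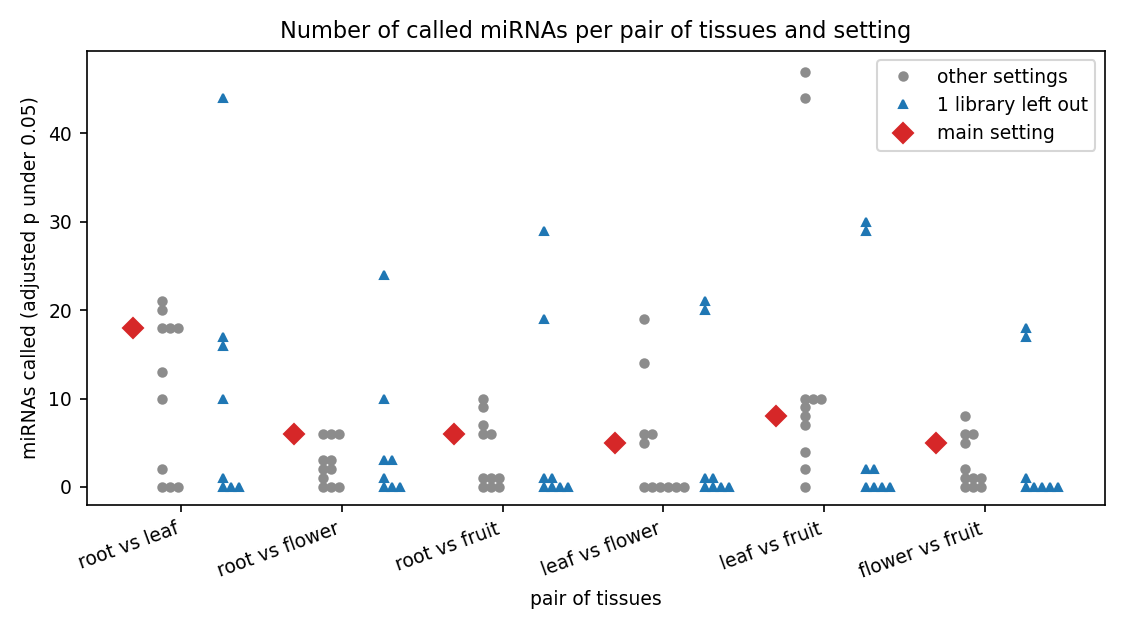
Number of miRNAs called per pair of tissues (adjusted p under 0.05, limma) in the main setting (diamonds), with 1 library left out (triangles) and in the other settings (circles). The counts for leaf against fruit run from 0 to 47 around a main count of 8.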

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

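Library weights, entries as deposited and lists of known mature names were chosen only after the data were seen. Of the 42 directed differences of the 24 named miRNAs, 0 reversed in any setting that tested them. Most settings could not have reversed them, since they were named only where the libraries of the 2 tissues do not overlap. A minimum value of 10 and the fits without a root, leaf or flower library did not test all 42. All 42 were called with median-of-ratios scaling, a pseudocount of 0.5 and entries as deposited, but none of the 42 was called in all settings, even without counting those that left out a library. In the order root and leaf, root and flower, root and fruit, leaf and flower, leaf and fruit, flower and fruit, the counts of 18, 6, 6, 5, 8 and 5 became 10, 3, 1, 0, 7 and 1 with quantile normalization. They became 2, 2, 1, 0, 2 and 1 with no filter, 20, 2, 6, 0, 4 and 1 with a minimum value of 10, and 13, 0, 0, 0, 10 and 0 with a pseudocount of 10. Limma without the trend gave 18, 3, 9, 0, 10 and 2, library weights gave 0, 0, 0, 14, 44 and 8, and fits of only the 2 tissues compared gave 0, 0, 0, 19, 47 and 0. A pseudocount of 0.5 moved root and fruit to 10. The main fit shares 1 spread over all tissues. The median absolute log2 difference between replicates was 1.82 in root, 1.38 in flower, 0.536 in leaf and 0.554 in fruit. Library weights keep all 8 libraries, and fits of 2 tissues use the spread of those tissues alone. Both called 0 in each pair with root and more than the main fit between leaf and fruit. The root calls of the main fit thus rest on the shared spread. Fewer libraries alone do not account for the rise between leaf and fruit. The other shifts were not tested for a cause.

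The 10 miRNAs of the F test became 3 with quantile normalization, 4 with no filter or a minimum value of 10, 27 with a pseudocount of 0.5, 0 with a pseudocount of 10 and 35 with library weights. The 2 miRNAs each highest in root, leaf and flower became 0 in each with quantile normalization, no filter, a minimum value of 10, a pseudocount of 10 and library weights, and 1, 0 and 0 without the trend. The 2 list calls became 4 with quantile normalization, no filter, a minimum value of 10 or no trend, 6 with entries as deposited or known mature names only, and 0 with an estimated correlation. In the 42 fits of a pair that called 0 miRNAs, between 17 and 48 had an unadjusted p under 0.05.

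With a replicate block, the counts were 0, 1, 1, 0, 0 and 0 in the same order, 0 for the F test, 0 highest in each tissue and 4 list calls. Same-numbered libraries did not vary together in every pair: the correlation of their deviations was 0.238 for root and leaf, -0.197 for root and flower, -0.142 for root and fruit, -0.0118 for leaf and flower, -0.0878 for leaf and fruit and -0.0393 for flower and fruit. With 2 libraries per tissue, these correlations cannot show whether the number stands for a shared batch or plant. The counts with the block are therefore a limit on the main counts.

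Leaving out 1 library at a time, with the lone library of that tissue assumed to vary like the others, gave from 0 to 44 calls between root and leaf, 0 to 24 between root and flower, 0 to 29 between root and fruit, 0 to 21 between leaf and flower, 0 to 30 between leaf and fruit and 0 to 18 between flower and fruit. The F test ran from 0 to 53, miRNAs highest in root from 0 to 4, in leaf from 0 to 6, in flower from 0 to 4 and in fruit from 0 to 1, and list calls from 0 to 5. Depth limits what an entry of 0 shows: in root 2, where 3 reads correspond to a value of 7.62, 2 of the 18 root and leaf calls and 1 of the 6 root and flower calls rest on values within that floor. Where both libraries of a tissue were at 0, that tissue also added no spread to the fit. The p-values of calls against such a tissue may therefore be too small.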

Other observations

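The tests of explanations in this part were chosen only after the results were seen. Several abundant miRNAs that were not called over all miRNAs tested in any pair were present in every library. Among them, mes-miR403a_1ss19TC was called between flower and fruit only when adjusted over the silencing list alone. The 4 most abundant members of the silencing list were found in all 8 libraries, and ath-miR168a-3p, the opposite arm of the AGO1 regulator miR168, had a mean of 1592 in root, 986 in leaf, 940 in flower and 1599 in fruit. lus-miR162a, which targets DCL1, had a mean of 1544 in root, 847 in leaf, 1050 in flower and 2152 in fruit. ath-miR156j_1ss14AT, which like miR157 targets SPL genes, was between 462 and 1297 in all 8 libraries, while ath-miR157a-5p_2ss12TG15AG ran from 17.8 to 45306. gma-MIR156f-p3_1ss12CG was 5757 and 2500 in flower, at most 44 in root and leaf, 0 in fruit 1 and 698 in fruit 2. nta-miR172d, which targets AP2 genes, was between 80.4 and 1102. ptc-miR827_1ss20AC was 31.3 in root 1 and 1217 in root 2, and the SD of ath-miR160a-5p in root, 2444, exceeded its mean of 1862.

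Some sequences in the table look like pieces of longer structural RNAs. Of the 56 sequences of 18 nt, 10 end in CCA, against 8 of 214 longer ones (Fisher's exact test, two-sided, p = 0.000792), as the 3' ends of mature transfer RNAs would; 0 of these 10 are among the 24 miRNAs named in the comparisons, so the test does not bear on those. The test is consistent with transfer RNA fragments left after the authors' removal. The overlap of 9 bases between 2 MIR6173 sequences was reached in 0 of 10000 shuffled sets (permutation p = 1e-04, the smallest these shuffles can give), but this decides nothing, since both were named by a match to the same hairpin arm and the overlap was seen first. An origin of the MIR5368, MIR9410, MIR9483 and MIR6173 sequences in ribosomal, transfer or plastid RNA was not tested and remains open, as does a real difference in fragments between tissues.

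The 2 fruit libraries lay far apart in ath-miR157a-5p_2ss12TG15AG, 530-fold, and in vvi-miR167b, at 1316 and 18585, 14.1-fold; of 54 other miRNAs with a fruit mean of at least 100 and a value above 0 in both libraries, 4 were over 10-fold higher in fruit 2, ath-miR171a-3p_1ss17AG (11.3-fold), ath-miR319a (18.4-fold), ptc-miR530a_R+1_1ss20TG (30.9-fold) and ppe-miR530_L-2R+2 (50.5-fold), while gma-MIR156f-p3_1ss12CG was listed at 0 in fruit 1. Flower RNA mixed into fruit 2 would need a share of 44.2% of the flower mean for ath-miR157a-5p_2ss12TG15AG (34.2% of the higher flower library), but 9 other miRNAs high in flower implied a median of 1.28% of that mean, with an upper quartile of 21.1% and 0 of the 9 at or above 44.2%; with gma-MIR156f-p3_1ss12CG, left out of the 9 as a MIR156 name and at 16.9%, the median was 4.71% and the upper quartile 20.1%. Leaf RNA would need 52.5% of the leaf mean for vvi-miR167b, but 12 other miRNAs high in leaf implied a median of 0.0832%, with an upper quartile of 3.18% and 2 of the 12 at or above it. A scaling by 1 factor per library, which the steps point to but the sources do not state, moves all miRNAs alike. Such a scaling could not give 530-fold and 14.1-fold side by side. The 54 had a median ratio of fruit 2 to fruit 1 of 0.995, with an upper quartile of 1.48. Since the authors had already scaled these values, this ratio is a description and not a test of the scaling. A difference between the sampled fruits, for example in age or in the parts taken, may remain as an untested hypothesis.

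Names from families known mainly in grasses were found only in flower 1 and, for ata-miR528-5p, also in fruit 2, at 23.3 and 36.9; miR444, miR1432 and ata-miR528-3p_1ss10GT were above 0 in flower 1 alone. For ata-miR528-5p, greater depth is argued against as the source, since the deeper flower 2 held 0 reads of it where the flower 1 level would give 31.5. This check was not run on miR444, miR1432 and ata-miR528-3p_1ss10GT, at 1.08, 4.75 and 7.78 in flower 1. The miR444 value lies below the 3-read floor of 1.3 in flower 1. Of 40 other names taken from grass species, 10 were found in flower 1 or fruit 2 and nowhere else (5 in flower 1 alone, 1 in fruit 2 alone and 4 in both), against 3 of 226 remaining names (Fisher's exact test, two-sided, p = 4.2e-07), which is consistent with reads from a grass. A narrower measure decided nothing: 68.9% of the values of 6 names taken from wheat or its wild relative lay in these 2 libraries, between the bounds of 80% and 50% set for and against. Reads from a grass may thus be the source, as a hypothesis, and no biological explanation was tested.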
